A study of Mus musculus with 12 samples.

How the data were processed

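Expression was measured with Affymetrix arrays in ventricular myocytes of adult mice, isolated enzymatically with the Langendorff system and treated with 100 nM Iso or left untreated for 24 h. Total RNA was taken up with Trizol and labelled as biotinylated cRNA. The labels give 12 arrays in 4 groups of 3 biological replicates, from 6 mice. The array type and the array annotation build are not given in the sources used here.

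Per the submitters' processing notes, the authors summarised the arrays with RMA, whose version is not given in the sources used here. The deposited values are log2 and ran from 2.25 to 13.8, with array medians near 3.32, and were used as they are. There were 25428 probe sets, 1 per gene identifier. Of these, 24705 carried 1 gene symbol and 723 none; 24704 different symbols resulted, 1 of them with 2 probe sets, of which the brighter was used. The 723 without a symbol were fitted separately, and 0, 0, 0, 3 and 4 of them passed in the comparisons Iso in WT, Iso in DKO, interaction, DKO without Iso and DKO with Iso.

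Genes were kept if their probe set lay above the median of its array on at least 3 of the 12 arrays, which left 13737 and set 10967 aside as dim. limma 3.58.1 in R 4.3.3 fitted a mean for each of the 4 groups over all 12 arrays, with moderated variances (eBayes). Contrasts were Iso minus untreated in WT and in DKO, the difference of these (DKO minus WT), and DKO minus WT without and with Iso. P-values were adjusted by the Benjamini-Hochberg method over the genes kept, and a gene passed at an adjusted p under 0.05. Standard errors are those of limma, and the p-values of every comparison rest on 3 arrays per group and the moderated variance.

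Of 32 gene lists, 30 were tested with camera at its preset correlation between genes of 0.01, adjusted over the lists. The sex-linked genes and the CaMKII family were read gene by gene. The alternatives were camera with a correlation estimated from the data and the directional test fry. "Adjusted over the list alone" means the Benjamini-Hochberg method over the tested members of 1 list. The lists, the 5 comparisons, the filter, the thresholds, the rule for naming genes and the fixed set of genes were chosen before the data were examined. Members passing only over the list alone were named outside that rule, after their values were seen.

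Named were the 10 genes with the largest rise and the 10 with the largest fall among those that passed, or the 10 with the smallest p where fewer than 5 passed. To these came up to 4 passing members of each list and a fixed set given whatever the result. Predicted genes without a proper name were counted but not named. Of the fixed set, Hba-a1, Hbb-b1 and Adrb1 were not analysed here, and Hbb-bs was dim. Gene biotypes and the order of genes along chromosomes came from a gene table of assembly GRCm38.p6. For probe sets named after microRNA and other small RNA genes, the transcript detected was not determined here.

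Alternatives were no filter or a filter at the 25th percentile, the mean of the probe sets of a gene, median centring, quantile or cyclic loess scaling on top, eBayes with trend and robust settings, array weights, the mouse as a random or fixed block, only the 6 arrays compared, an added fold threshold of 0.5 log2, and each array left out in turn. A setting without both untreated DKO array 3 and Iso-treated WT array 3 was added after the data were seen. So were a setting without small non-coding RNA genes and the mean Iso effect over both genotypes. Of the 2 arrays only untreated DKO array 3 correlated poorly with the others (median 0.956, against 0.986 for Iso-treated WT array 3).

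The labels give the same mouse number to 1 untreated and 1 treated array. The deviations of these arrays from their group means correlated at 0.00733, 0.0864 and 0.130 in the DKO mice and -0.0623, 0.0566 and 0.0109 in the WT mice, with a consensus of 0.0333, across genes that are not independent replicates.

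The calls were tested on simulated data in which 200 of 13737 genes changed and noise followed the residual spread of each array. At a log2 change of 1, limma recovered 65.7% of the changed genes for Iso in WT, 74.6% for Iso in DKO, 47.8% for the interaction and 65.7% for each genotype comparison. At 0.5 the shares were 10.4%, 31.3%, 2.99%, 10.4% and 20.9%. False calls numbered 4 for Iso in WT, 23 for Iso in DKO and 3 for the interaction. They numbered 22 for DKO without Iso and 1 for DKO with Iso. Iso in DKO and DKO without Iso thus gave more than the others. The interaction, which also uses the untreated DKO arrays, did not. Since 200 genes changed in this single run, these numbers cannot be set against the calls on the real arrays. With 3 lists shifted by 0.3, camera recovered 3 and called 0 others. The simulated noise was independent between genes. This run therefore cannot show how camera fares when the genes of a list are correlated. Raw array files were not used here.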

Results

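Gene expression was measured in adult mouse ventricular myocytes, the contractile cells of the heart's lower chambers, isolated from 6 mice and kept in culture for 24 h. Of these mice, 3 lacked the delta and gamma forms of CaMKII, the calcium/calmodulin-dependent kinase II (double knockout, DKO), and 3 were wild type (WT). Myocytes of each mouse gave 1 array without treatment and 1 array after 100 nM isoprenaline (Iso), an agonist of the beta-adrenergic receptors that raise heart rate and contractile force. The 12 arrays thus form 4 groups of 3, and this number limits the precision of every value. Each mouse is a separate animal, so the errors include variation between animals. Expression is on the log2 scale, and 13737 of 24704 genes were bright enough to be tested.

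The untreated DKO array 3 stood apart from the other 11. Its correlation with them across genes, which are not independent replicates, was 0.949 to 0.965. Its residuals around the group mean had a root mean square of 0.374, against 0.141 to 0.276 on the other arrays. Small non-coding RNA genes lay 0.199 above their mean on this array, against -0.187 to 0.109 elsewhere. Its endothelial markers lay 0.681 above their mean, against 0.198 on the next highest array. Each comparison that uses the untreated DKO group includes this array, and values without it are given for part of the results.

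**Figure D1:**
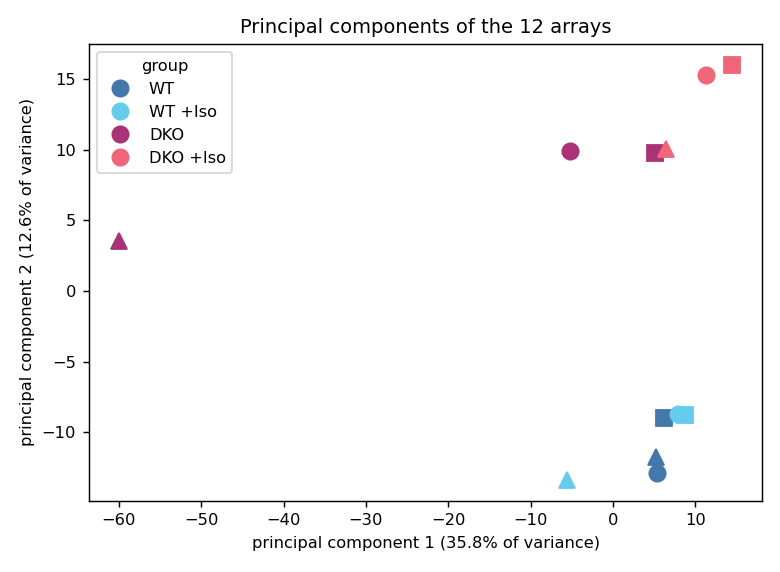
Principal components 1 (horizontal, 35.8% of the variance) and 2 (vertical, 12.6%) of the 12 arrays over the tested genes, in arbitrary units; each point is 1 array, coloured by group, with circles, squares and triangles for replicates 1, 2 and 3. The untreated DKO array 3 lies alone at -59.9 on component 1, and the DKO and WT arrays lie on opposite sides of 0 on component 2.

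The knocked-out genes were examined first, array by array. Camk2g (Entrez gene 12325), which encodes the gamma form, read 4.78, 5.23 and 5.41 on the untreated WT arrays and 5.40, 5.71 and 5.80 on the Iso-treated WT arrays. On the DKO arrays it read 4.16, 3.57 and 4.20 without Iso and 3.89, 3.89 and 4.11 with Iso, so all 6 DKO arrays lay below all 6 WT arrays. The difference, DKO minus WT, was -1.17 (SE 0.20, limma adjusted p = 0.0361) without Iso and -1.67 (SE 0.20, adjusted p = 0.00238) with Iso. Without Iso this call was lost in 11 of 25 alternative settings, including those without untreated DKO array 1 or any 1 of the untreated WT or Iso-treated DKO arrays or Iso-treated WT array 2, where the highest adjusted p over all settings was 0.367. Camk2d (Entrez gene 108058), which encodes the delta form abundant in heart, read 7.94, 8.09 and 7.96 in untreated WT, 8.10, 8.42 and 7.99 in Iso-treated WT, 7.85, 7.91 and 7.36 in untreated DKO and 7.75, 7.98 and 7.72 in Iso-treated DKO. Its differences of -0.29 (adjusted p = 0.446) and -0.35 (adjusted p = 0.640) did not pass. The other family members, Camk2a and Camk2b, differed by 0.03 and -0.34 without Iso and by -0.38 and -0.03 with Iso, and did not pass. A probe set can lie outside the deleted part of a gene, in which case its signal does not check the genotype. On all 12 arrays the X-inactivation transcript Xist was dim (2.96 to 3.09) while the Y-linked gene Uty read 4.46 to 5.62.

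**Figure D2:**
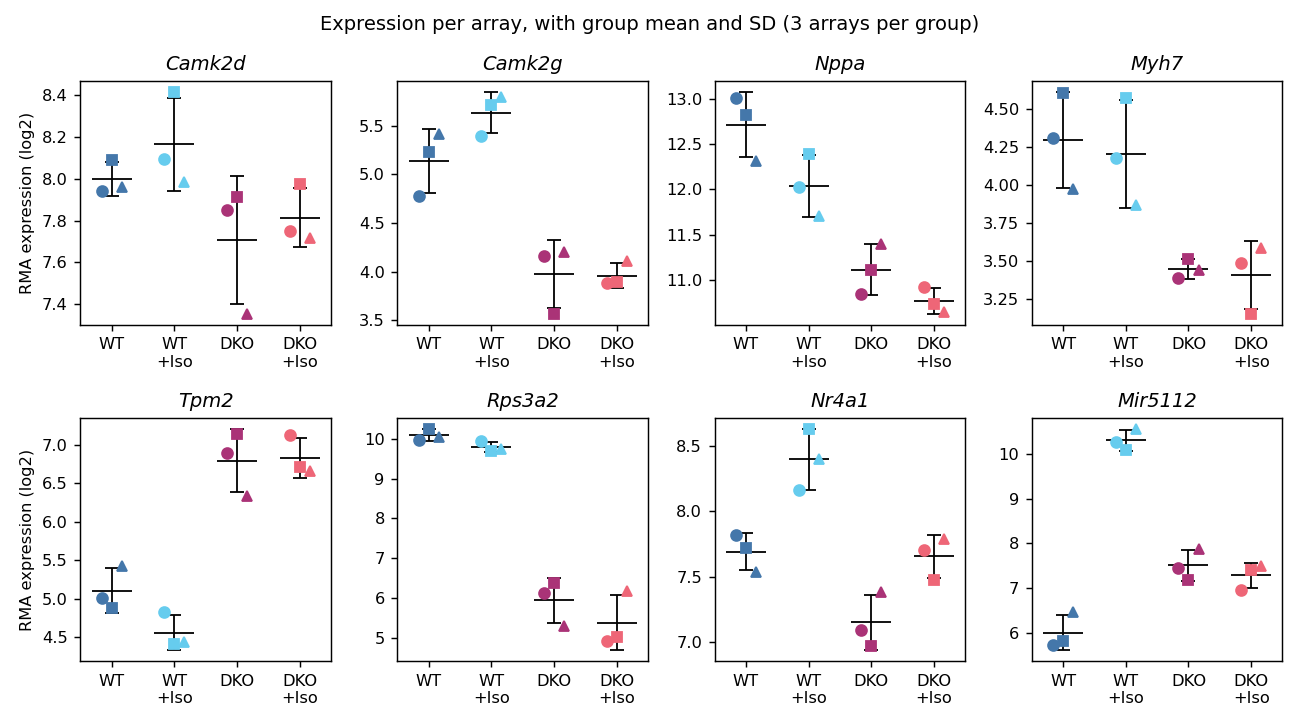
Expression (RMA, log2 units, vertical axes that do not start at 0 and differ between genes) of 8 genes on each array; each point is 1 array, with circles, squares and triangles for replicates 1, 2 and 3, and the horizontal line and bar are the group mean and SD (n = 3). Camk2g, Nppa and Rps3a2 are lower and Tpm2 higher on every DKO array than on any WT array, and Mir5112 stands at 10.3 on average in Iso-treated WT and at 6.00 to 7.50 in the other groups.

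The effect of Iso in myocytes with both kinases was taken from the treated and untreated WT arrays. Of the 13737 genes, 3 rose and none fell in limma's test, and 920 had an unadjusted p under 0.05 where 687 are given by chance. A probe set named for a microRNA gene, Mir5112, rose most. Its signal rose from 6.00 ± 0.397 to 10.3 ± 0.244 (SD, n = 3; log2 difference 4.30, SE 0.23, adjusted p = 2.2e-06), a 19.7-fold difference. Mir1932, also named for a microRNA gene, rose 5.85-fold (2.55, SE 0.23, adjusted p = 0.000418). Esr1, which encodes estrogen receptor alpha, rose from 4.91 ± 0.229 to 7.63 ± 0.873 (2.72, SE 0.38, adjusted p = 0.0394). For each of the 3 genes, 3 of 3 treated arrays lay above all untreated arrays, which genes selected by a small p nearly always show.

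The remaining 7 of the 10 genes with the smallest p in this comparison did not pass. They were Atp6v1g1, a subunit of the vacuolar proton pump (-2.19, adjusted p = 0.0521), the small nucleolar RNAs Snord71 (1.499, 0.0521) and Snord17 (2.36, 0.184), the nuclear non-coding RNA Neat1 (1.49, 0.117), Resf1 (0.73), the immunoglobulin gene Ighg2c (0.98) and the ubiquitin-conjugating enzyme Ube2a (-0.57), the last 3 with an adjusted p of 0.224. The 209 small non-coding RNA genes that were tested had a median difference of 0.18 as a class. This class was chosen after the leading genes were seen, and with its genes left out no gene passed limma's test and 891 had an unadjusted p under 0.05. The difference for Esr1, which is not of this class, was 2.72 in that fit as before, and its call ended through the adjustment. The count was 8 without untreated DKO array 3 and 5 without Iso-treated WT array 3. The call for Esr1 was lost on leaving out any 1 array except untreated DKO array 3 or Iso-treated WT array 2, with adjusted p between 0.00150 and 0.296 over all settings.

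Genes that beta-adrenergic signalling is known to act on were measured whatever their result. Nr4a1, an immediate early orphan nuclear receptor, differed by 0.71 (SE 0.16, adjusted p = 0.333), and the immediate early factor Fos by 0.56 (adjusted p = 0.460). The natriuretic peptide genes Nppa and Nppb differed by -0.68 (0.550) and -0.25 (0.742), and skeletal actin Acta1 by -0.34 (0.599). The myosin heavy chains Myh6 and Myh7 differed by 0.15 (0.909) and -0.09 (0.986), the calcium pump Atp2a2 by 0.00 and its inhibitor Pln by 0.37 (0.657). The phosphodiesterase Pde4d differed by -0.11, and the cytokine Il6 and chemokine Ccl2 by -0.17 and 0.55 (0.789). None of these genes passed.

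As groups, 8 of the 30 gene lists tested were higher with Iso than without in WT (camera with a preset correlation). Of 28 inflammatory cytokines and NF-kB targets, 18 lay above 0 (median 0.06, adjusted p = 0.00844; adjusted p = 0.412 with an estimated correlation). None passed over all genes, but 6 rose when adjusted over the list alone, among them the chemokines Cxcl2 (1.10) and Ccl3 (1.21), interleukin 1 beta (Il1b, 0.89) and its receptor antagonist Il1rn (0.75), named after their values were seen. Of 37 immediate early and CREB-responsive genes, 25 lay above 0 (median 0.07, adjusted p = 0.0151; adjusted p = 0.485 with an estimated correlation), with Nr4a1 alone passing over the list alone. Interferon-stimulated genes had a median of 0.20 (19 of 25 above 0, adjusted p = 0.0194; adjusted p = 0.412 with an estimated correlation).

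Lists of muscle function were higher too. Medians were 0.10 for calcium handling (20 of 27 above 0, adjusted p = 0.00844), 0.12 for fatty acid oxidation (23 of 33, adjusted p = 0.00844) and 0.06 for the sarcomere (21 of 27, adjusted p = 0.0422). No member of these lists passed, over all genes or over the list alone, and adjusted p = 0.412, 0.412 and 0.548 with an estimated correlation. Markers of other cell types also moved: endothelial markers had a median of 0.21 (15 of 18 above 0) and neuronal, Schwann and mesothelial markers one of 0.31 (7 of 8, with Upk1b at 0.95 passing over the list alone), both with adjusted p = 0.00844. With an estimated correlation their adjusted p = 0.485 and adjusted p = 0.412. The atrial genes Sln and Myl7, looked at after the values were seen, read 8.33 and 8.16 on Iso-treated WT array 1 and 8.11 and 7.93 on array 2, against 3.27 and 4.82 on array 3. Without Iso-treated WT array 1 only 3 lists passed, and without array 2 also 3. The directional test fry called 0 of the lists, the lowest of its adjusted p-values being 0.248. In lists that did not pass as a whole, members passing over the list alone were Nr4a1 in the list of MEF2 factors and class IIa histone deacetylases (0.71), Rgs2, a brake on G protein signalling (0.80), Cd14, a co-receptor for bacterial lipopolysaccharide (0.67), the muscle ubiquitin ligase Fbxo32 (0.64), the deubiquitinase Usp2 (-0.47) and Sdf2l1 of the endoplasmic reticulum (-0.98). Apart from Nr4a1 they were, like Upk1b, named after their values were seen.

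The same treatment was then examined in DKO myocytes. Here 6 genes rose and 1 fell in limma's test, and 2527 genes had an unadjusted p under 0.05. Cpox, an enzyme of heme synthesis, rose from 5.73 ± 0.107 to 6.99 ± 0.181 (SD, n = 3; 1.26, SE 0.16, adjusted p = 0.0190), a 2.39-fold difference. The transcriptional regulator Tcf20 rose 2.04-fold (1.03, SE 0.13, adjusted p = 0.0168). Gp6, the collagen receptor of platelets, rose by 1.02 (SE 0.15, adjusted p = 0.0275), but not with the mouse as a block (adjusted p = 0.0678). Its signal was low, at 3.15, 2.94 and 2.89 on the untreated DKO arrays, below the array medians near 3.32. Sco2, an assembly factor of cytochrome c oxidase, fell by 1.34 (SE 0.19, adjusted p = 0.0275) from 9.88 ± 0.328 to 8.55 ± 0.276. The other 3 genes are predicted or unnamed transcripts. In all 7 genes, 3 of 3 treated arrays lay beyond all untreated arrays, which genes selected by a small p nearly always show.

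These calls depended on single arrays. The count was 2 without untreated DKO array 1, 605 without array 2 and 31 without array 3, and all 7 calls were kept in the latter 2 settings. Without Iso-treated DKO array 1 or array 2 limma called 0 genes, with 1815 and 1604 at an unadjusted p under 0.05. Cpox and Tcf20 were lost without any 1 of untreated DKO array 1 and Iso-treated DKO arrays 1 and 2, Cpox also without untreated WT array 3, and Gp6 and Sco2 without these and others (highest adjusted p 0.260). The count was 4 without untreated WT array 1 or array 2 and 2 without array 3. With only the 6 DKO arrays in the fit it was 0, with 1726 at an unadjusted p under 0.05. With the mouse as a block 10 genes passed, 4 of them among the 7. In a run of simulated data with the spread of each array, this comparison gave 23 false calls, against 4 for Iso in WT. Far more genes passed in that run than here, and the adjustment allows false calls as a share of the genes that pass. The 23 therefore cannot be set against the 7 calls.

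Among genes measured whatever their result, Nr4a1 differed by 0.50 (SE 0.16, adjusted p = 0.133) and Fos by 0.02. Atp2a2 differed by 0.40 (adjusted p = 0.200), Myh6 by 0.27 (0.267), Acta1 by -0.32 (0.180) and Nppa by -0.35 (0.406). Pln, Pde4d and Il6 differed by 0.20, 0.23 and 0.33, Ccl2 by 0.08, and Nppb and Myh7 by -0.01 and -0.04. None passed. Members of several lists that did not pass as a whole passed over the list alone. Among them were the ryanodine receptor Ryr2 (0.64), titin (Ttn, 0.87), Mef2a (0.71), Mef2c (0.48), the growth factor Vegfa (0.77), the CREB-responsive kinase Sik1 (0.68), the immediate early factors Junb (-0.68) and Egr1 (-0.44) and the enzyme of fatty acid metabolism Mlycd (-0.73). Sik1, Junb and Egr1 share a list, as do Mef2a and Mef2c. Over the list alone 2 immediate early and CREB-responsive genes rose and 2 fell. In fatty acid oxidation 2 rose and 1 fell, and among inflammatory genes 1 rose and 4 fell. The members named here were chosen after their values were seen, and none of them passed over all genes.

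Of the 30 lists, only macrophage and leukocyte markers changed with Iso in DKO. Their median was -0.28, with 16 of 20 below 0 (camera, adjusted p = 0.00295; adjusted p = 0.483 with an estimated correlation; fry, adjusted p = 0.0394). Over all genes none of the 20 passed, and over the list alone 5 fell. They were the complement components C1qa (-0.75) and C1qb (-0.90) and the antigen presentation genes Cd74 (-0.81), H2-Ab1 (-1.02) and H2-Aa (-0.42). Without untreated DKO array 3 the median was -0.18 (adjusted p = 0.00634). The endothelial list had a median of -0.27 and did not pass (adjusted p = 0.0584); without that array its median was -0.10 (adjusted p = 0.236). With the mouse as a block 2 lists passed, as they did without untreated DKO array 2 or 3, Iso-treated DKO array 1 or 3, or untreated WT array 2. Without untreated DKO array 3, the list of MEF2 factors and class IIa histone deacetylases passed upward (adjusted p = 0.00100), against adjusted p = 0.195 with it. This list also holds other transcription factors of the heart, such as Gata4, Tbx5 and Srf. Its RNA levels do not measure CaMKII signalling to these proteins.

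Whether the Iso effect differed between genotypes was tested as an interaction, the effect in DKO minus the effect in WT. In this test 2 genes passed, Mir5112 (-4.52, SE 0.33, adjusted p = 7.9e-05) and Mir1932 (-2.83, SE 0.32, adjusted p = 0.00642). Mir5112 went from 6.00 to 10.3 with Iso in WT and from 7.50 to 7.28 in DKO, and Mir1932 from 3.76 to 6.30 in WT and from 4.10 to 3.82 in DKO. Both are small non-coding RNA genes, a class whose median interaction was -0.20, or -0.10 without untreated DKO array 3, and with the class left out limma called 0 genes, with 1360 at an unadjusted p under 0.05. Over all genes 1388 had an unadjusted p under 0.05, against 687 by chance.

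The next 8 genes by p did not pass. The interaction was -3.37 for Esr1, -1.32 for the chemokine Ccl5, -3.22 for Rmrp, the RNA of RNase MRP, -2.81 for Mir187, 1.06 and -1.55 for the ubiquitin-conjugating enzymes Ube2d1 and Ube2l6, and 1.31 for Cpox, each with adjusted p = 0.102, and -2.10 for Snord71 (adjusted p = 0.0952). With the mouse as a block, 5 genes passed, among them both microRNA genes and Esr1 and Mir187, each with adjusted p = 0.0232. Without untreated DKO array 2 the count was 16, and without array 3 it was 7, the calls for Mir5112 and Mir1932 being kept in both. For Nr4a1 the interaction was -0.20 (adjusted p = 0.761), for Fos -0.54 (0.469), for Camk2g -0.51 (0.539) and for Nppa 0.33 (0.713). It was 0.24 for Nppb, 0.11 for Myh6, 0.05 for Myh7, 0.03 for Acta1, 0.40 for Atp2a2, -0.17 for Pln, 0.34 for Pde4d, 0.50 for Il6, -0.47 for Ccl2 and -0.06 for Camk2d, none of which passed.

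For 4 lists of non-myocyte and inflammatory genes the Iso effect was lower in DKO than in WT. Endothelial markers had a median interaction of -0.53, with 15 of 18 below 0 (adjusted p = 0.000390; adjusted p = 0.313 with an estimated correlation) and no member passing. Macrophage and leukocyte markers had a median of -0.28 (15 of 20 below 0, adjusted p = 0.0157; adjusted p = 0.288 with an estimated correlation). In this list 0 members passed over all genes and 4 over the list alone, namely Cd74 (-1.11), H2-Ab1 (-1.09), Cd14, a co-receptor for bacterial lipopolysaccharide (-0.75), and C1qa (-0.69). Inflammatory genes had a median of -0.23 (19 of 28 below 0, adjusted p = 0.0172; adjusted p = 0.329 with an estimated correlation), with Ccl5 (-1.32) and Ccl3 (-1.86) passing over the list alone. Neuronal, Schwann and mesothelial markers had a median of -0.40 (7 of 8 below 0, adjusted p = 0.0203; adjusted p = 0.288 with an estimated correlation). The endothelial median lay 0.681 above the mean of all arrays on untreated DKO array 3; without this array the endothelial median was -0.31 (adjusted p = 0.00288), the macrophage median -0.08 (adjusted p = 0.0275), and 9 lists passed in all. Fry called 0 lists (lowest adjusted p = 0.0717). Only 2 lists passed without untreated DKO array 1 and 2 without Iso-treated WT array 1, while 7 passed without untreated WT array 3 and 6 without Iso-treated WT array 3. The members singled out were named after their values were seen.

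Without Iso, DKO and WT myocytes differed in 28 genes, 14 higher and 14 lower in DKO (limma; 1897 at an unadjusted p under 0.05). Nppa, which encodes atrial natriuretic peptide, was 3.04-fold lower in DKO, at 11.1 ± 0.279 against 12.7 ± 0.360 (SD, n = 3; -1.61, SE 0.21, adjusted p = 0.00733). Tpm2, the beta form of tropomyosin, was 3.22-fold higher (1.69, SE 0.22, adjusted p = 0.00723), and Il15, a cytokine that sustains natural killer and T cells, was 3.01-fold higher (1.59, SE 0.25, adjusted p = 0.0200). The largest differences were in the ribosomal protein pseudogene Rps3a2 (-4.14, SE 0.31, adjusted p = 0.000118) and in esterase D (Esd; -2.93, SE 0.25, adjusted p = 0.000218). Rps3a2 resembles other copies of its gene closely, so that its signal cannot be assigned to 1 copy with certainty. In each of the 28 genes, 3 of 3 DKO arrays lay beyond all WT arrays, which genes selected by a small p nearly always show.

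Also higher without Iso were Rmrp (2.45), Snord71 (1.81), the phosphatase inhibitor Ppp1r14b (1.76), Mir5112 (1.504), Ube2l6 (1.26), the G protein subunit Gnb3 (1.01), sulfite oxidase Suox (0.96) and the lipogenic regulator Thrsp (0.92). Also lower were Hyi (-2.00), Abhd1 (-1.81), Ociad2 (-1.77), the platelet chemokine Ppbp (-1.46), renalase (Rnls, -1.31) and the glutathione transferase Mgst1 (-0.91). Hyi, Abhd1 and Rnls are listed as transcribed pseudogenes in the table of assembly GRCm38.p6. Small non-coding RNA genes as a class had a median of 0.17, and of 0.05 without untreated DKO array 3. In a run of simulated data with the spread of each array, this comparison gave 22 false calls. Far more genes passed in that run than here, so the 22 cannot be set against the 28 genes called on the real arrays. The count was 18, 180 and 46 without untreated DKO array 1, 2 or 3, and 7 and 9 without untreated WT array 1 or 2; without untreated DKO array 3, 27 of the 28 calls were kept. With only the 6 untreated arrays in the fit 2 calls were kept, those for Rps3a2 and Esd. The call for Nppa was lost in that fit and without untreated WT array 1 or 2, its difference running from -1.85 to -1.46 and its adjusted p from 0.000117 to 0.133 over all settings. Tpm2 was lost in the same 3 settings (highest adjusted p 0.141), and Il15 in these, without untreated DKO array 1 and without the filter (highest adjusted p 0.245). In the fit of 6 arrays all other calls named here were lost too. Single arrays ended the calls for Abhd1 (untreated WT array 2), Suox (WT array 1), Hyi and Rnls (WT arrays 1, 2), Rmrp, Mir5112 and Ube2l6 (DKO array 1, WT arrays 1, 2), Gnb3 (WT arrays 1 to 3), Thrsp (DKO array 1, WT arrays 1 to 3), Ppp1r14b (these and Iso-treated DKO array 1) and Ppbp (untreated DKO arrays 1 and 3, WT arrays 1 to 3, Iso-treated DKO arrays 1 and 2), with a highest adjusted p of 0.367, for Ppp1r14b.

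By list, 22 genes of the hypertrophic and fetal programme, which the stressed heart turns on again, held 1 that was lower over all genes, Nppa, and 4 lower when adjusted over the list alone: Nppa, the stress-responsive Ankrd1 (-0.91), Myh7 (-0.85, adjusted p = 0.125 over all genes) and Timp1 (-0.77). The list as a whole did not pass (median -0.08, adjusted p = 0.410). Nppb (-0.04), Acta1 (0.13), Myh6 (0.12), Atp2a2 (-0.30), Pln (0.07), Fos (0.02), Nr4a1 (-0.54, adjusted p = 0.192), Pde4d (-0.33), Il6 (-0.66) and Ccl2 (-0.56) did not pass over all genes. Endothelial markers were the only list that changed, with a median of 0.46 and 15 of 18 above 0 (adjusted p = 5.6e-05; adjusted p = 0.812 with an estimated correlation; fry, adjusted p = 0.199). Over all genes no endothelial marker passed, and over the list alone 9 rose, among them the receptor for vascular endothelial growth factor Kdr (0.70), Robo4 (0.74), Gpihbp1 (0.71) and Ptprb (0.70). The 3 members below 0 included the most abundant marker, Fabp4, which read 11.6, 11.7 and 10.9 in untreated DKO and 11.9, 11.6 and 11.8 in untreated WT. Cldn5, also below 0, read 7.16, 7.19 and 7.36 against 8.31, 7.33 and 7.52. The endothelial list lay 0.681 above its mean on untreated DKO array 3, and without that array its median was 0.36 (adjusted p = 0.000809). Without that array the list of MEF2 factors and class IIa histone deacetylases also passed, downward (adjusted p = 6.8e-05; with it, median -0.23 and adjusted p = 0.161). Its upward change with Iso in DKO in the same setting uses the same untreated DKO arrays with opposite sign, so these results are not independent. Among 28 inflammatory genes, over the list alone, 3 rose and 3 fell, with Ccl3 at 1.78 and the secreted protein lipocalin 2 (Lcn2) at -1.50. The list members named here, other than those fixed beforehand, were chosen after their values were seen.

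After Iso, the comparison that the study names, DKO and WT differed in 42 genes, 15 higher and 27 lower in DKO (limma; 1087 at an unadjusted p under 0.05). Il15 was 5.08-fold higher in DKO, at 6.90 ± 0.185 against 4.55 ± 0.279 (SD, n = 3; 2.35, SE 0.25, adjusted p = 0.000892). Tpm2 was 4.83-fold higher (2.27, SE 0.22, adjusted p = 0.000480). Nppa was 2.42-fold lower, at 10.8 ± 0.142 against 12.04 ± 0.342 (-1.28, SE 0.21, adjusted p = 0.0262). The chemokine Ccl5, which recruits T cells and monocytes, was 2.50-fold lower (-1.32, SE 0.15, adjusted p = 0.00230), and heme oxygenase Hmox1, an enzyme of the antioxidant response, was 1.87-fold lower (-0.90, SE 0.16, adjusted p = 0.0327). In each of the 42 genes, 3 of 3 DKO arrays lay beyond all WT arrays, which genes selected by a small p nearly always show.

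Other genes higher in Iso-treated DKO were Atp6v1g1 (2.18), Prrg4 (1.53), the collagen-modifying enzyme P3h2 (1.44), the Z-disc protein myotilin (Myot, 1.36), neprilysin (Mme, 1.16), the ketone body enzyme Bdh1 (1.15), Thrsp (1.01) and the RNA polymerase subunit Polr2h (0.85). Polr2h read 3.34, 3.51 and 3.55 on the Iso-treated DKO arrays and 2.51 to 3.15 on all others, below the array medians near 3.32. It thus passed the filter only through the group in which it was called higher. Lower were Rps3a2 (-4.41), Mir5112 (-3.02), Abhd1 (-2.82), Esr1 (-2.59), Mir1932 (-2.49), Esd (-2.38), the beta-globin gene Hbb-bt (-2.05, adjusted p = 0.0375), Mir187 (-1.84) and the chemokine Cxcl3 (-1.81, adjusted p = 0.0327). Hbb-bt is nearly identical to its neighbour Hbb-bs, which was too dim to be tested, so the signal cannot be given to 1 of the copies. The count was 163 without untreated DKO array 3, with all 42 calls kept. It was 11, 10 and 18 without Iso-treated DKO array 1, 2 or 3, and 14 and 13 without Iso-treated WT array 1 or 2. The call for Nppa was lost without any 1 of these 5 treated arrays, with adjusted p from 0.00271 to 0.155 over all settings, and that for Hmox1 without any 1 of the 6 treated arrays or untreated WT array 1 (highest adjusted p 0.171), while those for Il15, Tpm2, Ccl5, Rps3a2, Abhd1 and Esd held in all 25. Bdh1 was lost without Iso-treated DKO array 1 or 2 (highest adjusted p 0.0821), Esr1 without these or WT array 1 (0.0953), Atp6v1g1 and Thrsp without any Iso-treated DKO array or WT array 1 or 2 (0.102 and 0.0837), Prrg4 without Iso-treated DKO array 1 or 2 or any WT array (0.148), and Myot and Mme without any 1 of the 6 treated arrays (0.129 and 0.102). Mir187 was lost in 13 of 24 settings (0.271), Hbb-bt in 11 of 25 (0.240), Polr2h in 10 (0.201), P3h2 in 9 (0.165) and Cxcl3 in 9 (0.191). Each of these 5 was lost without Iso-treated DKO array 1, 2 or 3 or WT array 1 or 2, and all but Polr2h without the filter. Further losses were without Iso-treated WT array 3 for Mir187, Hbb-bt and Polr2h, without untreated DKO array 1 for Mir187, Hbb-bt and Cxcl3, and without untreated WT arrays for each (1 to 3 for Mir187, Polr2h and P3h2, 1 and 2 for Hbb-bt, 3 for Cxcl3). Myh7 (-0.80, adjusted p = 0.166), Nr4a1 (-0.74, adjusted p = 0.0948), Fos (-0.52, adjusted p = 0.324), Ccl2 (-1.02, adjusted p = 0.261), Nppb (0.20), Myh6 (0.23), Acta1 (0.15), Atp2a2 (0.10), Pln (-0.10), Il6 (-0.15) and Pde4d (0.01) did not pass.

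The lists that differed after Iso were all lower in DKO, 8 in number, led by immune genes. Of 20 macrophage and leukocyte markers 18 lay below 0 (median -0.27, camera adjusted p = 2.5e-06; adjusted p = 0.0918 with an estimated correlation; fry, adjusted p = 0.0168). Over all genes Cd74 (-0.94, SE 0.17, adjusted p = 0.0400) and Cd14 (-0.92, SE 0.17, adjusted p = 0.0402) were lower. Over the list alone the receptor chains Fcgr1 (-0.80) and Fcer1g (-0.66) passed as well. The calls for Cd74 and Cd14 were each lost on leaving out any 1 of the 6 treated arrays or untreated WT array 1, that for Cd74 also without untreated DKO array 1 or WT array 2 and that for Cd14 without untreated WT array 3 (highest adjusted p 0.250 for both). Of 28 inflammatory genes 23 lay below 0 (median -0.21, adjusted p = 8.6e-05; adjusted p = 0.136 with an estimated correlation; fry, adjusted p = 0.0522). Ccl5 was the 1 member lower over all genes. Over the list alone 6 were lower, among them Ccl2, Il1b (-0.93), Lcn2 (-1.09) and the prostaglandin synthase Ptgs2 (-0.69), and 1 was higher, the oncostatin M receptor Osmr (0.66). Interferon-stimulated genes had a median of -0.19 (18 of 25 below 0, adjusted p = 0.0271; adjusted p = 0.368 with an estimated correlation), and none passed. The smooth muscle and pericyte markers had a median of 0.07 and the endothelial markers one of 0.02 (adjusted p = 0.509 and 0.606), the endothelial mean being -0.06. The list members named here, other than those fixed beforehand, were chosen after their values were seen.

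Among the other 5 lists, oxidative stress and NRF2 target genes had a median of -0.07 (16 of 23 below 0, adjusted p = 0.0271; adjusted p = 0.136 with an estimated correlation; fry, adjusted p = 0.0388). Hmox1 was lower over all genes, and over the list alone also the quinone reductase Nqo1 (-0.67) and the regulator of the response, Nfe2l2 (-0.71). Immediate early and CREB-responsive genes had a median of -0.08 (27 of 37 below 0, adjusted p = 0.0155; adjusted p = 0.368 with an estimated correlation), with Nr4a1 passing over the list alone. Extracellular matrix genes had a median of -0.09 (22 of 31 below 0, adjusted p = 0.0234; adjusted p = 0.368 with an estimated correlation), with thrombospondin Thbs1 (-1.03) passing over the list alone. Atrial and conduction markers had a median of -0.19 (11 of 13 below 0, adjusted p = 0.000209; adjusted p = 0.136 with an estimated correlation; fry, adjusted p = 0.0438), Nppa being the 1 member lower over all genes, with Myh7 also passing over the list alone. Sln, a member of this list, was high on Iso-treated WT arrays 1 and 2, where it read 8.33 and 8.11 against 3.27 on array 3. Neuronal, Schwann and mesothelial markers had a median of -0.49 (6 of 8 below 0, adjusted p = 0.00109; adjusted p = 0.128 with an estimated correlation; fry, adjusted p = 0.0388), with Upk1b (-0.998), Krt8 (-0.55) and Msln (-0.48) passing over the list alone. Without Iso-treated WT array 1, 4 of the 8 lists were lost and 4 passed. The interferon list was also lost without Iso-treated WT array 2 or DKO array 2, as was the matrix list, and the oxidative stress list without Iso-treated DKO array 3. Of the members named here, Nqo1, Nfe2l2, Thbs1, Upk1b, Krt8, Msln and Sln were chosen after their values were seen.

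**Figure D3:**
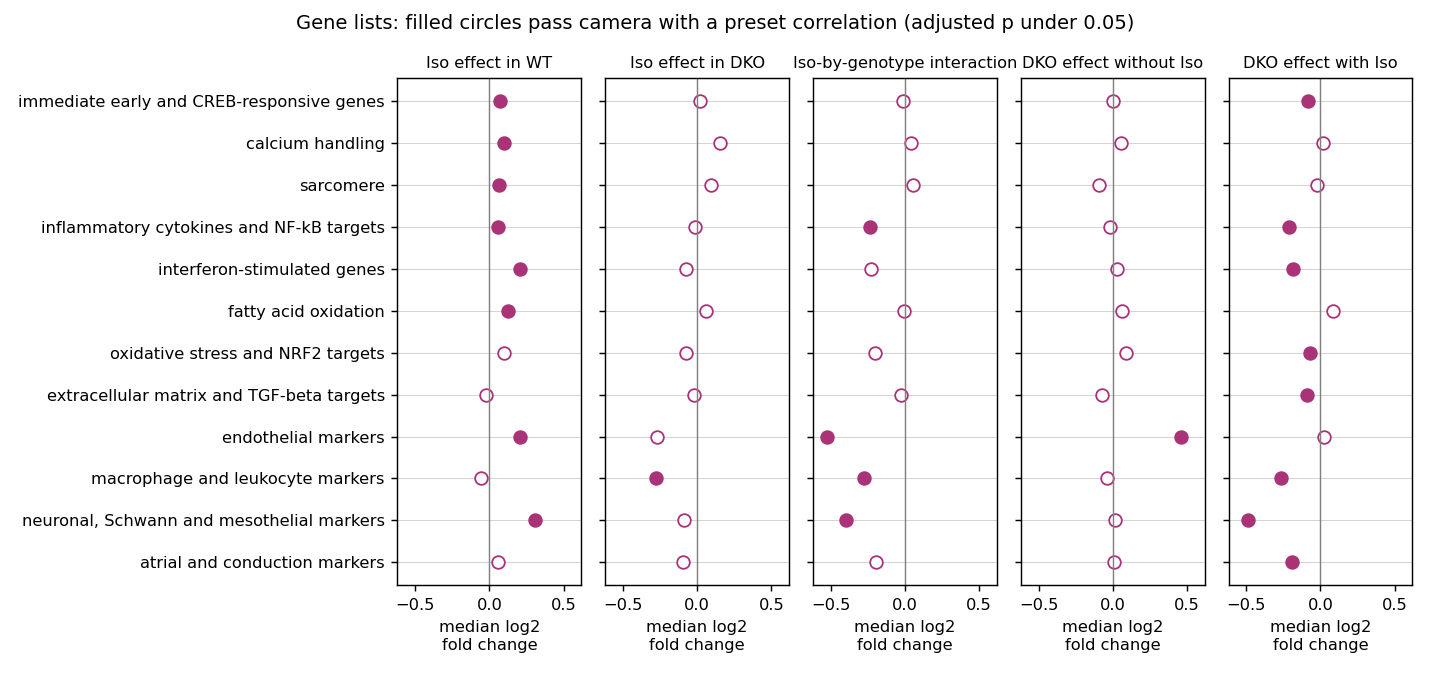
Median log2 fold change (horizontal) of the 12 gene lists that passed camera with a preset correlation in at least 1 comparison; each circle is 1 list in 1 comparison and filled circles mark adjusted p under 0.05, all of which were lost with an estimated correlation. Macrophage and leukocyte markers were lower after Iso in DKO (-0.28) and in DKO than WT with Iso (-0.27), and endothelial markers were higher in DKO than WT without Iso (0.46).

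The study's stated question concerns phosphorylation of histone H3 at serine 28, a mark that displaces Polycomb proteins from chromatin. The arrays measure RNA, so neither this mark nor Polycomb binding was measured here. A list was written of kinases and phosphatases of the mark other than CaMKII, Polycomb subunits and the related genes Ywhaz, Ywhae, Kdm6a and Kdm6b. This list (24 tested) did not pass in any comparison. Its median was 0.07 for Iso in WT (adjusted p = 0.449), 0.11 for Iso in DKO (0.195), 0.08 for the interaction (0.496) and -0.15 for DKO without Iso (0.410), where it was -0.03 without untreated DKO array 3. With Iso the median for DKO was 0.06 and the mean -0.01 (adjusted p = 0.867), so median and mean differed in sign. Of 40 developmental regulators listed as bound by Polycomb, 9 were bright enough to be tested. The others did not enter the test, so it cannot speak for members of the list that are silent in these cells. The medians of the 9 were 0.01, -0.02, -0.06, 0.09 and 0.04 in the same order of comparisons, with adjusted p of 0.850, 0.876, 0.743, 0.410 and 0.509.

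Further lists that passed camera in none of the 5 comparisons are given by their medians for DKO against WT with Iso. Among signalling lists these were 0.16 for other calmodulin kinases and calcineurin, 0.02 for beta-adrenergic and PKA signalling, -0.03 for MEF2 factors and class IIa histone deacetylases and -0.10 for growth factors and hormones of myocytes. The hypertrophic and fetal programme had a median of 0.03 but a mean of -0.23 and a test direction downward (adjusted p = 0.113). Ion channels and connexins had a median of -0.08, glycolysis and glucose use 0.06, oxidative phosphorylation 0.02 and the circadian clock 0.11. The unfolded protein and heat shock response had 0.01, apoptosis and p53 targets -0.01 (mean 0.02, of the other sign), muscle atrophy, ubiquitin and autophagy 0.02 (mean -0.04, of the other sign) and proliferation 0.10. Fibroblast markers had -0.12 (adjusted p = 0.0986), and the 3 tested haemoglobin and erythroid genes -0.31 (adjusted p = 0.0570), the lowest adjusted p of the 22 lists that did not pass; fry called this list lower (adjusted p = 0.0438).

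The genotype calls with and without Iso overlapped. Of the 28 genes called without Iso and the 42 called with Iso, 18 were shared, 17 of them with the same sign. Among these 17, 5 were higher and 12 lower in DKO, where independent lists would share 0.0153 and 0.0275 genes. The 4 groups share no array between these comparisons, but each mouse contributes to both. Mir5112 was the 1 shared gene of opposite sign, at 1.504 without and -3.02 with Iso. Across all genes the correlation of the genotype differences was 0.0517, and 0.216 without untreated DKO array 3; genes are not independent replicates. The Iso calls in WT and DKO shared 0 genes, and the Iso differences correlated at 0.0644 (0.167 without untreated DKO array 3).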

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

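The Iso effect differed between genotypes for 2 genes and 4 gene lists, each marked by a test of the difference itself (limma for genes, camera for lists). The values, DKO minus WT, were -4.523 for Mir5112 and -2.828 for Mir1932. Median values were -0.5276 for endothelial markers, -0.2758 for macrophage and leukocyte markers, -0.2327 for inflammatory cytokines and NF-kB targets and -0.3963 for neuronal, Schwann and mesothelial markers. Without untreated DKO array 3 these medians were -0.3137, -0.0795, -0.2867 and -0.383 in this order. With an estimated correlation none of the 4 lists passed (adjusted p = 0.313, 0.288, 0.329 and 0.288 in this order), nor with fry (lowest adjusted p = 0.0717). The regrouping of arrays into other groups was planned before the values were seen. Of 100 splits of the 12 arrays, the real one included, 7 called at least the 2 genes of the real split, and 21 shifted at least its 4 lists, the highest other values being 17 genes and 6 lists. Of the 15 splits that part all 6 pairs of arrays from a mouse, 4 called as many genes and 4 as many lists, so chance is not excluded for either count. The split with 17 calls points to structure of the samples, since it amounts to the mean Iso effect over both genotypes.

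The other comparisons allow 10 splits of 6 arrays, too few for a share under 0.05, so neither result can be drawn from them. As many genes as in the real split were called by 1 split, the real one, for Iso in WT (3, highest other 0), Iso in DKO (7, highest other 1), DKO without Iso (28, highest other 0) and DKO with Iso (42, highest other 0). As many lists were called by 2 splits for Iso in WT (8, highest other 8), 6 for Iso in DKO (1, highest other 2), 6 for DKO without Iso (1, highest other 2) and 2 for DKO with Iso (8, highest other 8). For Iso, 4 of the 10 splits part as many pairs as the real one; among these the highest others were 0 genes and 5 lists in WT and 1 gene and 1 list in DKO.

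All 3 tests on the untreated DKO array 3 were chosen after it was seen to stand apart. A WT sample under this label is argued against, since its Camk2g lay 0.578 below the lowest WT array, more than the SD within groups of 0.27. An exchange of labels within DKO was not tested, since Camk2g averaged 3.97 in untreated and 3.96 in Iso-treated DKO. RNA quality or labelling cannot be told apart from other causes: its small non-coding RNA genes lay 0.199 above their mean, above the highest other array (0.109) but by less than the SD of 0.0932. Its deviations from the gene means correlated at -0.247 with the log length of the gene, against -0.108 to 0.199 on the other arrays. No threshold had been set for this value, and genes are not independent replicates. Other cell types in the preparation cannot be told apart either. The endothelial list lay 0.681 above its mean, but its 5 most abundant members had a median of 0.17, under the 0.3 of the highest other array, and ranged from -0.901 for Fabp4 to 0.749 for Egfl7 (SD 0.645).

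For the genes that differed by genotype both with and without Iso, both tests were written before the values were seen. A region carried along with the targeted genes is argued against as the source of most of them: of the 18 shared genes the target Camk2g was left out, and 5.88% of the other 17, Mir5112 among them, or 1 gene, lay within 200 tested genes of Camk2d or Camk2g (95% interval 0.149 to 28.7%). Linked strain variants elsewhere cannot be told apart from an effect of the kinases: 2 pairs of these genes lay within 50 tested genes of each other, where a permutation test with 10000 random draws of genes gave 0.939 on average (p = 0.231). Single unlinked variants stay open, and the strain is not given in the sources used here.

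Both tests on the lower macrophage and inflammatory lists in Iso-treated DKO myocytes were chosen after the result was seen. On these arrays, an equal fall of all non-myocyte types is argued against for smooth muscle and endothelial markers. Smooth muscle and pericyte markers lay 0.337 above macrophage markers (bootstrap 95% interval 0.168 to 0.572) and endothelial markers 0.288 above (0.101 to 0.529). All these values rest on the same few arrays, and marker genes are not independent replicates. The intervals therefore need not cover the variation between mice. Fibroblast markers lay 0.15 above, with an interval that includes 0 (-0.00922 to 0.426), so a lower share of fibroblasts along with macrophages stays open. Neuronal, Schwann and mesothelial markers were lower too (median -0.49), so a lower share of these cells also stays open. The macrophage list was chosen after it was seen to be lower, which favours such gaps. Fewer leukocytes in the DKO preparations cannot be told apart from lower expression in the same cells. Without Iso the 20 macrophage markers had a median of -0.0402, against -0.266 with Iso, and the interval without Iso (-0.213 to 0.00574) leaves it open.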

How the results depend on the processing

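No called gene or list turned direction in any setting, while some lists that did not pass did so without untreated DKO array 3. Counts depended on the arrays, the filter, the weights and the correlation between genes. The cause was not tested for any of the moves except where fewer arrays or genes enter by construction. Leaving out untreated DKO array 3 cannot alter the differences for Iso in WT or for DKO with Iso. Their counts of 8 and 163 in that setting thus moved through the spread estimate that the groups share. For Iso in WT (3 genes, 8 lists), genes numbered 5 with trend and robust settings and 6 with array weights. They numbered 5 with the mouse as a random block and 6 with only the 6 arrays compared. Without both untreated DKO array 3 and Iso-treated WT array 3 they numbered 12, without small RNA genes 0, and with 1 array left out 2 to 8. Lists numbered 0 with an estimated correlation, 0 with fry and 3 to 9 with 1 array left out. For Iso in DKO (7 genes, 1 list), genes numbered 17 without the filter, 1109 with array weights, 0 with 6 arrays, 48 without both arrays and 0 to 605 with 1 left out. Lists numbered 2 without the filter, 2 at the 25th percentile, 2 with array weights, 2 with the replicate block, 2 without both arrays, 0 with an estimated correlation and 1 to 2 with 1 array left out. For the interaction (2 genes, 4 lists), genes numbered 51 with array weights, 5 with the replicate block, 7 without both arrays, 0 without small RNA genes and 2 to 16 with 1 array left out. Lists numbered 9 without both arrays, 0 with an estimated correlation, 0 with fry and 2 to 9 with 1 array left out.

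For DKO without Iso (28 genes, 1 list), genes numbered 18 without the filter, 698 with array weights, 2 with 6 arrays, 73 without both arrays and 7 to 180 with 1 array left out. Lists numbered 3 without the filter, 2 at the 25th percentile, 2 with array weights, 2 without both arrays, 0 with an estimated correlation, 0 with fry and 1 to 2 with 1 array left out. For DKO with Iso (42 genes, 8 lists), genes numbered 164 with array weights, 77 with 6 arrays, 101 without both arrays and 10 to 163 with 1 array left out. Lists numbered 0 with an estimated correlation, 5 with fry and 4 to 11 with 1 array left out. Median centring, quantile and loess scaling, the mean of probe sets and the fold threshold changed no count by more than 1.5-fold. The arrays already had nearly equal minima, medians and maxima, and only 1 symbol had 2 probe sets. Centring, quantile scaling and the mean of probe sets could therefore hardly change a count. They are nonetheless among the settings in which calls are counted as held or lost.

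With the mouse as a paired replicate block, Gp6 was lost for Iso in DKO (adjusted p = 0.0678), and Esr1 and Mir187 were gained in the interaction (adjusted p = 0.0232 for each). With the replicate number as a block across genotypes, which joins different mice, Mir187 (0.0548) and Cd74 (0.0642) were lost for DKO with Iso; deviations of equal numbers correlated at -0.0525 to 0.128. The replicate block changed no other call of a gene named in the 5 comparisons, while of the 17 calls of the mean Iso effect it kept 7. The fit of only 6 arrays was not run for the lists, nor for the interaction, which needs all 12. Low signal limits what can be seen: 10967 genes lay above the array median on fewer than 3 arrays and entered only the fits without that filter. Signal over background was not measured here.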

Other observations

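The mean of the Iso effects in both genotypes was added after a regrouping of the arrays was seen to call more genes than the interaction. On this mean 13 genes rose and 4 fell (limma; 1980 at an unadjusted p under 0.05, where 687 are given by chance), and those named were chosen after their values were seen. The nuclear-retained RNAs Neat1 and Malat1 rose by 1.20 (SE 0.18, adjusted p = 0.0306) and 0.82 (SE 0.12, adjusted p = 0.0306), with 1.49 and 0.91 for Neat1 and 0.77 and 0.87 for Malat1 in WT and DKO. Dot1l, a histone H3 methyltransferase, rose by 0.66, the elongation factor Ell2 by 0.71, the channel kinase Trpm7 by 0.66 and the interleukin 1 receptor antagonist Il1rn by 0.69. Mhrt, a heart RNA transcribed from the myosin heavy chain locus, rose by 0.45 (adjusted p = 0.0490). Sco2 (-0.95), Nudt6 (-0.69), Chid1 (-0.63) and Sertad1 (-0.51) fell. Nr4a1 differed by 0.61 and did not pass (adjusted p = 0.0613). Mir5112 and Mir1932 passed through the WT arrays alone. Most calls were lost in part of the 24 other settings: Neat1, Malat1 and Nudt6 in 7, Sco2 in 8, Dot1l and Trpm7 in 10, Ell2 and Chid1 in 11, Il1rn and Sertad1 in 12 and Mhrt in 13, mainly on leaving out single arrays (highest adjusted p 0.174, for Il1rn). The call for Mir1932 was lost in 7 of the 23 settings run for it. With the mouse as a replicate block, the calls for Dot1l, Trpm7, Ell2, Chid1, Il1rn, Sertad1 and Mhrt were lost.

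By list, calcium handling had a mean Iso effect with a median of 0.18 (camera, adjusted p = 0.00863; adjusted p = 0.504 with an estimated correlation), the sarcomere 0.08 (0.0302; 0.742) and fatty acid oxidation 0.11 (0.0456; 0.742). Macrophage and leukocyte markers had a median of -0.16 (0.0155; 0.504). Without untreated DKO array 3 fatty acid oxidation did not pass (adjusted p = 0.0718) while Nr4a1 (adjusted p = 0.0185), the immediate early and CREB-responsive list (0.0130, against 0.292 with it) and the list of MEF2 factors and class IIa histone deacetylases (0.00386, against 0.122) did.

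Of 100 splits of the 12 arrays, 1, the real one, called as many as 17 genes, and the highest other called 2. This grouping was chosen because it called the most genes among splits of the same arrays, so its rank is no test against chance, which stays open. The count moved with the arrays: 102 without untreated DKO array 3 (all 17 kept), 39 without untreated DKO array 2, 2 without untreated DKO array 1, Iso-treated DKO array 1 or 2 or untreated WT array 1 or 3, 11 without Iso-treated DKO array 3, 5 without untreated WT array 2 or Iso-treated WT array 1, and 3 without Iso-treated WT array 2. It was 581 with array weights, 10 with trend and robust settings and 13 with the mouse as a replicate block (7 of the 17 kept). Without both untreated DKO array 3 and Iso-treated WT array 3 it was 256.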
